A study of Mus musculus with 40 samples.

How the data were processed

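RNA was measured in 40 libraries from 8 C57BL/6J mice, 4 labelled male and 4 labelled female. Each animal gave 5 libraries: stellate ganglion (SG), thoracic ganglion T3, thoracolumbar ganglion T13/L1 (written T13_L1), lumbar ganglion L2, each pooled over both body sides, and fat taken from around the ganglia. These are sympathetic ganglia, which hold the cell bodies of postganglionic sympathetic neurons with their satellite glia. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with the Lexogen QuantSeq kit, which reads the ends of polyadenylated transcripts, and forward reads of 50 bp were sequenced from a pool. QuantSeq yields about 1 fragment per transcript, so counts were not divided by gene length. No molecular identifiers are described, so PCR copies may be among the reads. Floors cover counting error only, while the intervals of slopes given below rest on the spread between libraries.

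The submitters' processing notes name genome build GRCm38, R 3.4.3, DESeq2 1.18.1 and DESeq, without giving the step each was used for. The aligner, the counting program, the annotation and the use of strand in counting are not given in the sources used here. Reads of genes that overlap on opposite strands, and of near-identical paralogs, therefore cannot be assigned with certainty. The authors deposited 4 tables. The count table of the authors holds whole-number counts for 47643 genes without normalization, and is the one used for every test here. A second deposited count table holds 18531 of these genes. Its smallest sum over the 40 libraries is 60, and 0 of its cells differ from the first table. The deposited table of normalized counts (a signal scale) holds the count divided by 1 size factor per library, from 0.427 to 1.63. Size factors recomputed from the counts by the DESeq2 method differed from these by a relative 6.66e-16 at most. The deposited log2 table holds log2 of the count plus 1, minus the mean of that quantity over the genes of the same library. Columns were matched to samples by name, and gene symbols were found in the reference annotation of GRCm38 for 47224 of the 47643 gene identifiers. Coordinates are those of that annotation.

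Totals ran from 3030270 to 13169209 counts per library, 311801646 in all. The lowest totals were in T13_L1, T3 and L2 libraries. A floor of 3 counts, the upper 95% limit for a count of 0, equals 0.364 CPM (counts scaled by library total) in the SG library of animal 1. The highest correlation of log2 CPM between any 2 libraries was 0.9833, so no 2 libraries hold the same counts.

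Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (robust fit, TMM normalization, default expression filter, Benjamini-Hochberg adjustment, threshold 0.05). CPM values use the TMM-scaled library totals. The fat comparison was fitted on 40 libraries (15295 genes tested), and the comparisons among ganglia on the 32 ganglion libraries (14803 genes tested), each with tissue and labelled sex as terms. Upper ganglia are SG and T3 and lower ganglia are T13_L1 and L2, each side as the mean of its 2 groups. Labelled sex was tested on 8 samples per fit: the 4 ganglia of an animal summed, or 1 tissue at a time. The 38 gene lists, all of them reported below, were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. List members past the edgeR test were counted after adjustment over all genes and after adjustment over the list alone.

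Genes were named by a rule: past the threshold, not a gene model, a mean of at least 20 CPM on 1 side, and the same sign of the within-animal difference in at least 7 of 8 animals. The rule takes the 12 highest and 12 lowest log2 fold changes of each main comparison, the 5 highest and 5 lowest of the others, and up to 4 called members per direction of each list. Th, Dbh, Slc6a2, Npy, Chat, Vip, Sst, Adipoq, Ucp1, Xist and Ddx3y were reported whatever their test. A few genes that the rule takes are not reported here. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Genes named outside the rule are said to have been chosen after their values were seen.

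The 5 libraries with the same number come from the same animal per the labels, so the numbers pair the libraries. As a check, the deviations of the ganglion libraries from their tissue means correlated by 0.0716 on average within animals and by -0.0398 between animals. The correlations of each library were also averaged over the ganglia of each animal. For 19 of the 32 ganglion libraries this mean was highest for its own animal. Within animal 13 the mean correlation was -0.0494. The fit with the animal as a block is an alternative, because no source states the design the authors used. The other alternatives set beforehand were DESeq2 1.42.0, RLE normalization, no expression filter, the genes of the authors' shorter count table, counts thinned to 3030270 per library, the adipocyte score as a covariate, genes called higher in fat left out, each animal left out in turn in the labelled-sex tests, only animals born in February, and voom on 32 libraries with the animal as a random effect. Alternatives added after seeing the data left out 4 libraries that stand apart (T3 of animal 1, L2 of animals 4 and 11, fat of animal 11), 3 T3 libraries with sensory neuron transcripts, the labelled-sex term, or Gm42418 with the mitochondrial transcripts, or used the pan-neuronal score as a covariate. A score is the mean log2 CPM of a list. Members of a list, such as Adipoq, Plin1 and Cfd for the adipocyte score, are thus adjusted for a mean that holds them. The scripts were tested on simulated data drawn from the real means and spreads with 200 changed genes. Apart from these changes each gene had the same mean in all tissues, and genes were drawn independently of one another. No animal effect or mixture of tissues was simulated, and genes of low expression were not among those changed. The shares and false calls below may therefore differ from those in the real libraries. In the upper versus lower simulation over 14803 genes, 41.8% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 2 false calls among 154. In the simulation of labelled sex over summed ganglia, on 16909 genes, these shares were 32.8%, 74.6% and 95.5%, with 8 false calls among 143 for edgeR and 36 among 189 for DESeq2.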

Results

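Gene expression was compared between 4 sympathetic ganglia and the fat that surrounds them in 8 C57BL/6J mice fed chow at room temperature. The stellate ganglion (SG) lies at the level of the upper thorax, T3 in the thoracic chain, T13_L1 at the thoracolumbar border and L2 in the lumbar chain. Each tissue had 8 libraries, 1 per animal. Total counts ran from 7233183 to 10552767 in SG, 3363361 to 6366822 in T3, 3030270 to 10390190 in T13_L1, 3494435 to 11121264 in L2 and 8112855 to 13169209 in fat. The labels give 4 males and 4 females. Labelled females 14 and 16 were born in December, and all other animals in the following February. Labelled sex therefore overlaps in part with birth date. Sex-linked transcripts went against the label in 5 of the 8 animals, so sex is written as labelled throughout. Values are CPM (counts scaled by library total with TMM), as mean ± SD over the 8 libraries of a tissue where a tissue is named. Fold changes are log2 values from edgeR's quasi-likelihood fit. The ± beside a fold change is an approximate standard error worked out from the test, which returns none itself. It is the absolute fold change divided by the square root of the test's F statistic. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test unless another tool is named. Coordinates are on GRCm38.

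The ganglion libraries differed in how much neuron and fat RNA they held. The mean log2 CPM of 22 pan-neuronal transcripts was 8.59 ± 0.09 in SG, 7.42 ± 1.01 in T3, 8.27 ± 0.27 in T13_L1, 7.82 ± 0.71 in L2 and 2.73 ± 1.76 in fat (SD, n = 8 each). That of 28 adipocyte transcripts was 5.85 ± 0.59 in SG, 7.48 ± 0.73 in T3, 6.23 ± 0.57 in T13_L1, 7.48 ± 0.77 in L2 and 9.41 ± 0.32 in fat. T3 of animal 1 had the lowest pan-neuronal score of the ganglion libraries, 5.07, and fat of animal 11 the highest of the fat libraries, 6.75. The transcript Gm42418 took 18% of the counts in SG, 10.1% in T3, 21.7% in T13_L1, 19.2% in L2 and 14.8% in fat on average, and mitochondrially encoded transcripts took 3.12%, 7.87%, 4.26%, 6.8% and 15.9%.

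**Figure D1:**
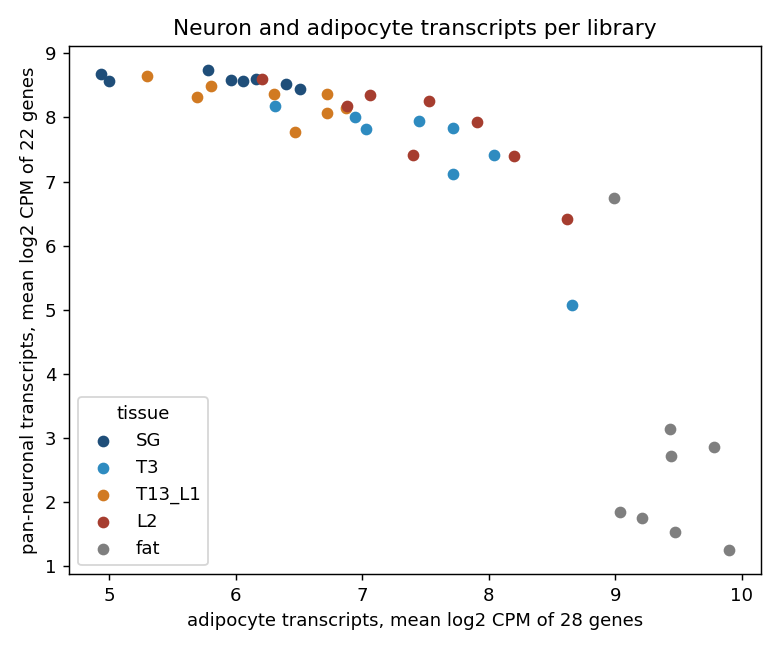
Each point is 1 of the 40 libraries, colored by tissue, with the mean log2 CPM of 28 adipocyte transcripts on the x axis and of 22 pan-neuronal transcripts on the y axis. SG libraries lie between 8.44 and 8.74 on the y axis, 1 T3 library lies at 5.07, and 1 fat library lies at 6.75 while the other fat libraries lie between 1.25 and 3.14.

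The first comparison asked which transcripts set the ganglia apart from the adjoining fat. Transcripts for noradrenaline synthesis and reuptake were far higher in the ganglia. Th, tyrosine hydroxylase (chromosome 7, 142892752 to 142931128), was at 1169 against 61.2 CPM (4.45 ± 0.60, adjusted p = 3.41e-08). It was joined by Dbh, dopamine beta-hydroxylase (4.43 ± 0.65, adjusted p = 1.76e-07) and Slc6a2, the noradrenaline transporter (4.20 ± 0.66, adjusted p = 7.12e-07). Among the peptides, Npy reached 1362 against 51.1 CPM (4.83 ± 0.53, adjusted p = 3.13e-10), Gal 178 against 5.58 CPM (4.98 ± 0.48) and Vip 110 against 3 CPM (4.81 ± 0.41), and the much rarer Sst (4.06 ± 0.49) and Chat (2.74 ± 0.46) were higher as well. Fat of animal 11 carries much of these fat means: the fat medians were 15 CPM for Th, 14.6 for Dbh, 34.8 for Slc6a2, 16.1 for Npy, 1.97 for Gal and 1.63 for Vip. Without the 4 libraries that stand apart, that one among them, the fold changes were 6.43 for Th, 6.58 for Dbh, 6.37 for Slc6a2, 6.41 for Npy, 6.26 for Gal, 5.75 for Vip and 5.41 for Sst. The highest fold change of a named gene was that of Rprm (5.21 ± 0.49), followed by Cdk5r2, an activator of Cdk5 (5.18 ± 0.73), and the glutamate receptor subunit Gria4 (5.08 ± 0.41). This order did not hold without the 4 libraries that stand apart. There Cdk5r2 (7.19) and Gria4 (6.65) stood above Rprm (6.35), as did Th, Dbh, Slc6a2 and Npy. In the other direction, the brown fat uncoupler Ucp1 (chromosome 8, 83290352 to 83298452) was at 309 CPM in ganglia and 3643 CPM in fat (-3.94 ± 0.35, adjusted p = 2.84e-12), and the adipokine Adipoq at 275 and 1650 CPM (-2.89 ± 0.23, adjusted p = 6.21e-14). Each of these was on the same side in 8 of 8 animals. In all, 5181 genes were higher and 5362 lower in ganglia among 15295 tested, 3392 and 2558 of them by over 2-fold.

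Neuronal lists were higher almost throughout. All 17 tested members of the noradrenergic list were higher, with the transcription factor Hand2 (4.53 ± 0.66) among the largest changes. Higher too were all 22 pan-neuronal genes (Nefm 4.64 ± 0.61, Stmn3 4.63 ± 0.57), all 10 cholinergic genes (Slc5a7, the choline transporter, 4.40 ± 0.58, and Ret 3.63 ± 0.41) and all 4 tested nicotinic receptor subunits (Chrnb4 4.28 ± 0.56, Chrna3 4.21 ± 0.61). Of the neuronal excitability channels, 30 of 32 were higher (Kcnq3 4.50 ± 0.57, Scn9a 4.49 ± 0.56) and 0 lower. Of 16 neuropeptide genes 13 were higher and Penk was lower (-0.70 ± 0.24). Of 9 chromaffin cell genes 8 were higher, Chga by 4.63 ± 0.57, and Penk was the exception; this list shares genes with the noradrenergic and neuropeptide lists. Glial transcripts moved with them: 17 of 19 satellite glia and Schwann genes were higher, such as Fabp7 (4.04 ± 0.59) and Kcnj10 (3.81 ± 0.38), while S100b, which adipocytes also express, was lower (-0.70 ± 0.14). Of 16 myelin genes 10 were higher, Cnp by 2.52 ± 0.20 and Mag by 2.27 ± 0.35, and 1 lower. The cholesterol synthesis list also stood higher in ganglia, with 20 of 22 genes up: Sqle, squalene epoxidase, by 3.23 ± 0.34, and Msmo1 by 2.98 ± 0.20. Its lower members were Acat2 (-0.59 ± 0.09) and Insig1 (-0.44 ± 0.19, adjusted p = 0.0376, and 0.0634 with DESeq2, 0.0615 with RLE normalization, 0.0872 without an expression filter and 0.0635 without 3 T3 libraries). The median fold change was 4.2 for the noradrenergic list and 4.25 for the pan-neuronal list, and 6.29 and 6.26 without the 4 libraries that stand apart. Slc5a7 (6.13), Chrnb4 (6.25), Chrna3 (6.19), Kcnq3 (6.39), Scn9a (6.47), Fabp7 (5.77), Kcnj10 (4.60) and Sqle (4.07) were also larger in that fit. Cnp (2.81) and Mag (2.19) moved less. By camera, these calls had adjusted p = 2.87e-09 for the noradrenergic list, 3.25e-11 for the pan-neuronal, 1.70e-04 for the cholinergic, 0.0203 for the nicotinic, 9.65e-10 for the channel, 4.07e-04 for the neuropeptide and chromaffin, 7.99e-08 for the glial, 1.70e-04 for the myelin and 1.55e-06 for the cholesterol list. None held with an estimated correlation: the nicotinic list had adjusted p = 0.312 with an estimated correlation, and the others adjusted p = 0.281 with an estimated correlation.

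Fat and vessel lists were lower in the ganglia. Of 28 adipocyte genes 26 were lower, among them the lipid carrier Fabp4 (-3.49 ± 0.26), Dgat2 (-3.41 ± 0.24), Pck1 (-3.38 ± 0.24) and Pparg (-3.36 ± 0.26), and all 14 tested brown adipocyte genes were lower, Otop1 by -3.99 ± 0.26 and Cidea by -3.45 ± 0.30. Of 16 endothelial genes 14 were lower (Kdr -2.67 ± 0.17, Flt1 -2.06 ± 0.16), and all 10 tested mitochondrially encoded transcripts were lower (mt-Cytb -2.24 ± 0.17). So were 6 of 14 mural cell genes (Des -2.21 ± 0.52, Rgs5 -1.88 ± 0.15), 3 of 4 adrenal cortex genes (Mrap, which adipocytes also express, -2.74 ± 0.24) and 7 of 10 genes of Hox paralogs 1 to 5 (Hoxa5 -2.64 ± 0.17), against 2 higher (Hoxd4 1.69 ± 0.23). Camera gave adjusted p = 3.62e-09, 3.30e-07, 6.73e-06, 0.00186, 0.0313, 0.0327 and 0.0189 for these 7 lists in that order. The mural list had adjusted p = 0.609 with an estimated correlation, the mitochondrial list adjusted p = 0.405 with an estimated correlation, and the other 5 adjusted p = 0.281 with an estimated correlation.

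The other 21 lists had no camera call. Receptors split by tissue: 18 of 35 hormone and transmitter receptors were higher, led by the muscarinic receptors Chrm2 (4.77 ± 0.49) and Chrm1 (4.56 ± 0.52), and 13 were lower, including the adrenergic receptors Adrb1 (-3.36 ± 0.22), Adra1a (-3.32 ± 0.31) and Adrb3 (-2.95 ± 0.26). Of 13 neurotrophin and GDNF receptors and ligands 7 were higher, such as the neurotrophin receptor Ngfr (4.53 ± 0.55), and 6 lower, such as the ligand Nrtn (-3.01 ± 0.28) and Ntrk3 (-1.56 ± 0.17). Of the 35 axon guidance genes 21 were higher and 9 lower. Hoxc9 was higher (3.60 ± 0.33) with 5 of the 6 tested Hox paralogs 9 to 13, whereas 6 of 7 paralogs 6 to 8 were lower (Hoxa7 -2.61 ± 0.19). Several immune lists had more lower than higher members, with 9 of 19 macrophage genes lower and 4 higher (Folr2 -1.26 ± 0.25, Cx3cr1 1.64 ± 0.16), and 13 of 17 lymphocyte genes lower (Trbc2 -2.07 ± 0.50). Among the others, 7 of 10 thymocyte genes were lower and 2 higher, 3 of 7 mast cell genes lower and 1 higher, and 4 of 8 MHC class II genes lower and 1 higher. The mesothelial and epithelial list had 6 of 7 genes lower and 1 higher, with Upk3b (-4.05 ± 0.45) and Lrrn4 (-3.68 ± 0.51) among the lowest of all named genes, near the neutrophil granule genes Ltf (-3.67 ± 0.49) and Camp (-3.65 ± 0.45). Of 18 fibroblast genes 8 were lower, and of 6 lymphatic endothelial genes 4 were lower and 2 higher. Counts of higher and lower members were 0 and 3 of 20 for skeletal muscle (Myh2 -3.38 ± 0.70), 1 and 2 of 9 for erythroid genes, 3 and 2 of 7 for dorsal root sensory neurons, and 6 and 13 of 29 for immediate early genes. They were 1 and 10 of 15 for clock genes, 6 and 6 of 21 for interferon genes, 3 and 2 of 10 for X inactivation and escape, and 0 and 0 of 4 for Y-linked genes. In the fit without the 4 libraries that stand apart, 14 skeletal muscle, 9 lymphocyte and 4 thymocyte genes were lower. Chrm1 (6.15), Chrm2 (6.08), Ngfr (5.94) and Hoxc9 (4.52) had larger fold changes there, with Chrm1 above Chrm2. Adrb1 (-3.43), Adra1a (-3.43) and Adrb3 (-3.02) moved little. The clock list reached adjusted p = 0.0388 by camera with the animal as a block, against 0.0695 without, and the axon guidance list adjusted p = 0.0434 without the 4 libraries that stand apart, against 0.0513 with them. Neither held with an estimated correlation in those fits (adjusted p = 0.331 and 0.249), and the clock list was at 0.0889 without the 4 libraries that stand apart. Adjusted over the list alone, the counts differed only for myelin (11 higher), hormone and transmitter receptors (14 lower), skeletal muscle (2 lower), adrenal cortex (4 lower) and erythroid genes (1 lower). Median and test differed in sign for hormone and transmitter receptors (median 0.8, camera down), skeletal muscle (median -0.7, camera up) and erythroid genes (median -0.57, camera up), and median and mean for X inactivation (-0.04 and 0.02).

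The second comparison asked how the upper ganglia, SG and T3, differ from the lower ones, T13_L1 and L2. Hox genes and the peptide genes Vip and Sst were among those that differed. Hoxc10 (chromosome 15, 102966796 to 102971893) averaged 0.163 CPM in the upper and 12.8 CPM in the lower ganglia (-6.06 ± 0.34, adjusted p = 8.16e-15). Hoxc9 (102976439 to 102985099 in the same cluster) averaged 7.12 and 44.8 CPM (-2.70 ± 0.15, adjusted p = 8.16e-15). Hoxc4 (103018934 to 103036852) ran the other way at 54.6 and 19.3 CPM (1.50 ± 0.13, adjusted p = 1.10e-09). Vip, which encodes vasoactive intestinal peptide (chromosome 10, 5639218 to 5647617), was at 41.7 CPM in the upper and 178 CPM in the lower ganglia (-2.09 ± 0.18, adjusted p = 1.97e-09). Sst, somatostatin (chromosome 16, 23889573 to 23890958), was at 8.94 and 25.9 CPM (-1.89 ± 0.23, adjusted p = 2.17e-06). Hoxc9, Hoxc10, Vip and Sst were lower in the upper ganglia in 8 of 8 animals, and Hoxc4 was higher in 8 of 8. Th (0.39 ± 0.19, adjusted p = 0.335), Dbh (0.03 ± 0.23, adjusted p = 0.984) and Slc6a2 (0.32 ± 0.24, adjusted p = 0.61) did not pass the test. Th passed without the 4 libraries that stand apart (0.37, adjusted p = 0.0162) and with the pan-neuronal score as a covariate (0.38, adjusted p = 0.0187), as Slc6a2 did with that score (0.34, adjusted p = 0.0163). In all, 149 genes were higher and 395 lower in the upper ganglia among 14803 tested. Without the 4 libraries that stand apart, 600 were higher and 1001 lower, 531 of the 544 calls among them, and at 3030270 counts per library 73 were higher and 229 lower.

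**Figure D2:**
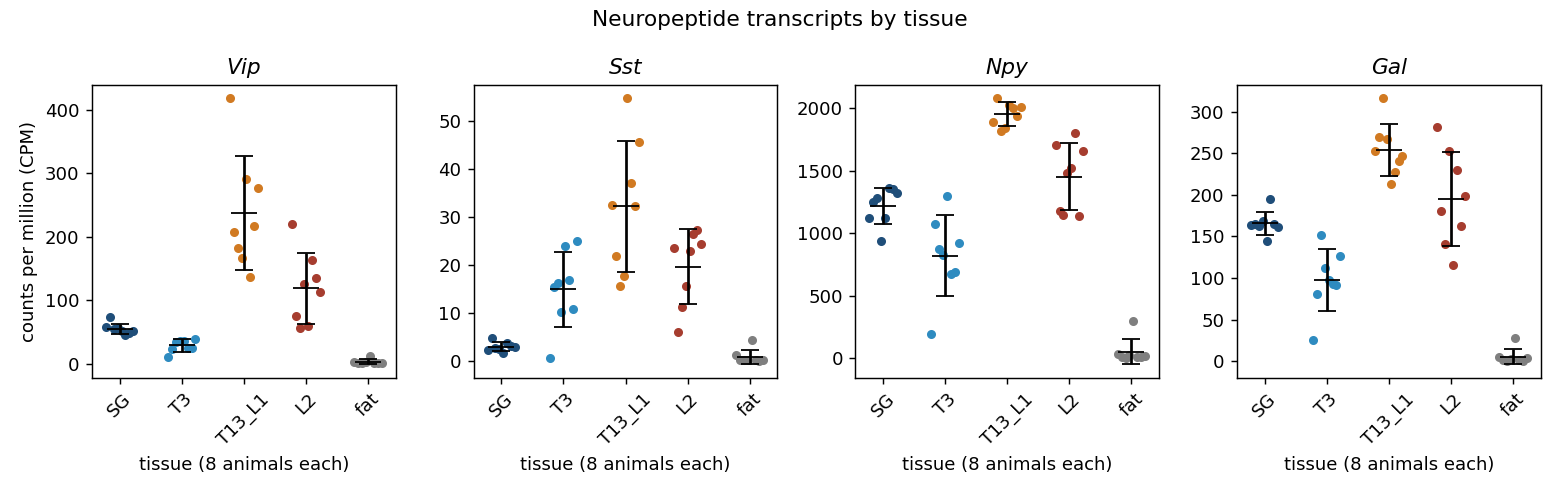
Each point is the CPM of Vip, Sst, Npy or Gal in 1 library, by tissue (8 libraries each), with bars for the mean ± SD. Vip lies between 137 and 418 CPM in T13_L1 and between 10.6 and 39 CPM in T3; Sst lies between 1.66 and 4.71 CPM in SG.

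By ganglion, Vip averaged 54.8 ± 8.36 CPM in SG, 28.7 ± 9.49 in T3, 237 ± 89.8 in T13_L1 and 119 ± 55.9 in L2 (SD, n = 8). Sst averaged 2.95 ± 0.953 CPM in SG, 14.9 ± 7.82 in T3, 32.2 ± 13.6 in T13_L1 and 19.7 ± 7.81 in L2. Npy (-0.76 ± 0.14, adjusted p = 0.00114) and Gal (-0.81 ± 0.14, adjusted p = 6.01e-04) were lower in the upper ganglia as well, while Pdyn (1.79 ± 0.42, adjusted p = 0.00912) and Cartpt (0.75 ± 0.21, adjusted p = 0.0416) were higher. Cartpt lost its call without an expression filter (adjusted p = 0.0762) and without 3 T3 libraries (adjusted p = 0.0833). Over the 16 neuropeptide genes tested, 2 were higher and 5 lower, also when adjusted over the list alone. Their median was 0.08, their mean -0.13 and the camera direction down (adjusted p = 0.0213, 0.0803 with the animal as a block, 0.0932 without the 4 libraries that stand apart, and adjusted p = 0.619 with an estimated correlation). In the cholinergic list 4 of 10 genes were lower and 0 higher. They were Vip, the choline transporter Slc5a7 (-1.79 ± 0.31, adjusted p = 5.33e-04), the vesicular acetylcholine transporter Slc18a3 (-1.21 ± 0.25, adjusted p = 0.0029) and Chat, choline acetyltransferase (-1.14 ± 0.25, adjusted p = 0.00528), at 1.21 against 2.72 CPM. Camera gave adjusted p = 1.08e-04 for this list, and adjusted p = 0.305 with an estimated correlation.

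**Figure D3:**
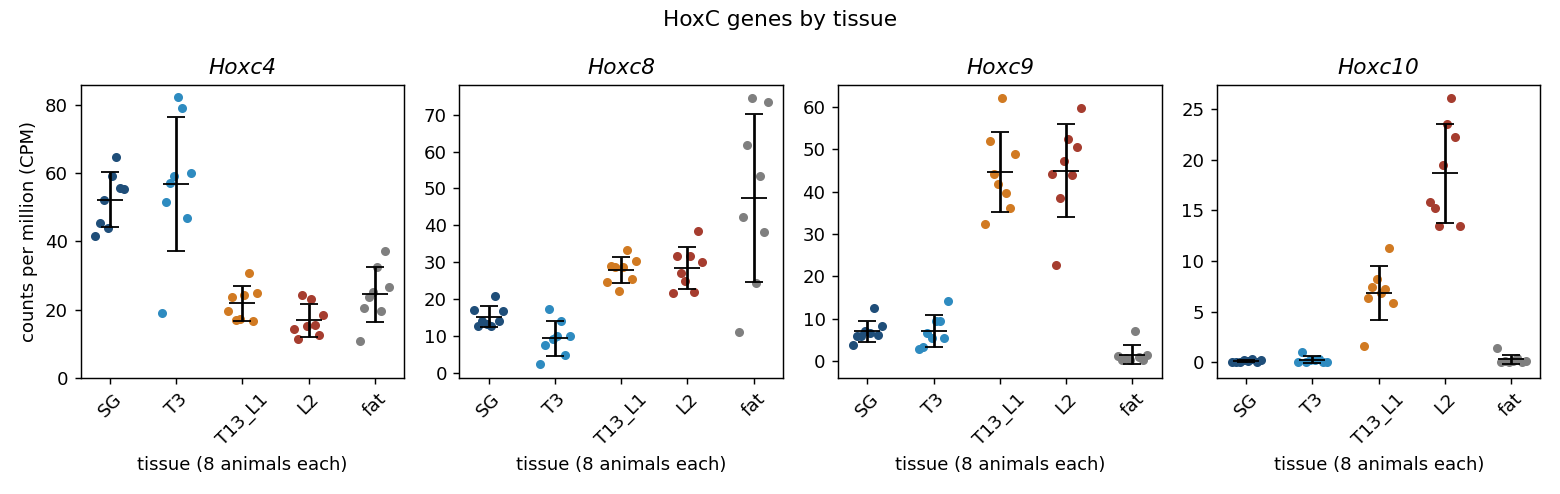
Each point is the CPM of Hoxc4, Hoxc8, Hoxc9 or Hoxc10 in 1 library, by tissue (8 libraries each), with bars for the mean ± SD. Hoxc9 lies between 3.77 and 12.5 CPM in SG and between 32.4 and 62 CPM in T13_L1, and Hoxc10 between 13.5 and 26.1 CPM in L2.

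Hox paralogs 9 to 13 had 5 of 6 tested genes lower in the upper ganglia (6 adjusted over the list alone), including Hoxa10 (-5.33 ± 0.42) and Hoxa9 (-3.85 ± 0.40). Paralogs 6 to 8 had 2 of 7 lower (4 adjusted over the list alone), Hoxc8 (-1.24 ± 0.15) and Hoxa7 (-0.67 ± 0.19, with adjusted p = 0.0657 without the 4 libraries that stand apart, 0.105 without 3 T3 libraries and 0.0904 at thinned counts). Paralogs 1 to 5 had 3 of 10 higher (5 adjusted over the list alone), Hoxc4, Hoxc5 (1.25 ± 0.17) and Hoxa4. These camera calls had adjusted p = 3.38e-25, 8.17e-05 and 9.09e-07, and adjusted p = 1.67e-08, 0.00413 and 0.0158 with an estimated correlation. Without the 4 libraries that stand apart the last 2 lost the latter call, at 0.0689 each, and the first kept it, at 4.00e-05. The mean log2 CPM of paralogs 1 to 5 was 2.87 in SG, 3.89 in T3, 2.75 in T13_L1 and 3.01 in L2. T3 and not SG thus carried the difference of this list. Hoxc4 was higher in both, at 52.3 CPM in SG and 56.9 in T3 against 21.8 in T13_L1 and 16.8 in L2. The median fold change of paralogs 1 to 5 was 0.39, and -0.08 once genes called higher in fat were left out. That setting took out most of the 10 genes, so the latter median rests on few. Hoxc10 averaged 0.101 ± 0.118 CPM in SG and 0.224 ± 0.348 in T3, at or below 5 counts in every library, so that its fold change rests on values near the floor.

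Myelin transcripts were lower in the upper ganglia, in 12 of 16 genes (14 adjusted over the list alone): the Schwann cell claudin Cldn19 (-2.05 ± 0.20, adjusted p = 1.56e-08), Ugt8a (-1.50 ± 0.28) and Ncmap (-1.43 ± 0.15), with 0 higher. Camera gave adjusted p = 7.62e-22 and adjusted p = 4.18e-04 with an estimated correlation, and 0.00719 for the latter without the 4 libraries that stand apart. Gjb1 (-3.20 ± 0.69), also on this list, is abundant in liver, whose transcripts were higher in some T13_L1 libraries. Over the 19 satellite glia and Schwann genes, only Gfra3 was called (-1.27 ± 0.15), with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 3.29e-04, and adjusted p = 0.351 with an estimated correlation). Immediate early genes were higher in 6 of 29 cases (7 adjusted over the list alone), with Fos at 1.29 ± 0.33 (1.04 at thinned counts, adjusted p = 0.146), Egr1 at 1.22 ± 0.18 and Junb at 0.85 ± 0.11, and camera gave adjusted p = 1.99e-05 and adjusted p = 0.0374 with an estimated correlation. The latter call was lost without the 4 libraries that stand apart (0.169). The mean log2 CPM of the immediate early list was 3.25 in SG, 3.53 in T3, 3.03 in T13_L1 and 3.22 in L2, so SG and L2 were close.

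Genes higher in the upper ganglia included C1ql1, a synaptic organizer of the complement C1q family (2.24 ± 0.34, 21.7 against 4.58 CPM), the cholecystokinin receptor Cckar (1.53 ± 0.24), the vesicular monoamine transporter Slc18a1 (1.41 ± 0.26) and the matrix protein gene Cilp (1.31 ± 0.21). They were followed by the short-chain fatty acid receptor Ffar3 (1.06 ± 0.19), Nxph3 (1.06 ± 0.22), the retinoic acid binding protein gene Crabp1 (1.05 ± 0.16) and the kinase gene Ptk2b (1.04 ± 0.12). Among 34 hormone and transmitter receptors, Npy2r (1.72 ± 0.40) and Npy1r (0.86 ± 0.25, and adjusted p = 0.0637 with the adipocyte score) were higher and Gcgr (-2.30 ± 0.44), a liver receptor, was lower. In the axon guidance list Robo2 was higher (1.10 ± 0.32, adjusted p = 0.0475, and 0.0526 with RLE normalization, 0.0594 without an expression filter and 0.184 without 3 T3 libraries). Slit2 and Epha7 (-0.70 ± 0.15, and -0.52 with adjusted p = 0.164 at thinned counts) were lower, out of 34 genes. Adjusted over the list alone, 4 receptors and 2 guidance genes were higher, and 1 receptor and 4 guidance genes lower.

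Some large fold changes belonged to transcripts of other cell types. S100a9 (3.24 ± 0.42) and S100a8 (2.76 ± 0.40), which encode calprotectin of neutrophils, were higher, and S100a9 was at 66.9 ± 85.5 CPM in T3 against 7.27 ± 6.79 in SG. The thymocyte genes Rag1 (4.05 ± 0.77) and Dntt were higher, as 2 of 10 in their list (4 adjusted over the list alone; camera adjusted p = 7.78e-05, adjusted p = 0.058 with an estimated correlation, and with an estimated correlation 0.0123 in the fit with the animal as a block and 0.263 without the 4 libraries that stand apart). T3 of animal 1, one of the 4, had the highest thymocyte score of T3 (4.13, mean 2.59). The median of Rag1 was 0 CPM in T13_L1 and in L2, so its fold change rests on values near the floor. Lower were the liver genes Apoa1 (-4.23 ± 0.81), Fga (-4.05 ± 0.87), Alb (-4.00 ± 0.83), Serpina1c (-3.91 ± 0.96, and adjusted p = 0.0844 at thinned counts and 0.0541 without 3 T3 libraries), Serpina3k (-3.90 ± 0.79) and Ahsg (-3.67 ± 0.83). Near them were the muscle genes Myh4 (-4.05 ± 0.73), Neb (-3.80 ± 0.74), Pvalb (-3.72 ± 0.71) and Ckm (-3.65 ± 0.65). The Serpina1 genes are near-identical paralogs and were not told apart with certainty. Of 20 skeletal muscle genes 17 were lower (19 adjusted over the list alone; camera adjusted p = 4.61e-20, and adjusted p = 0.0934 with an estimated correlation). Of 9 erythroid genes 6 were lower (8 adjusted over the list alone), with Hba-a1 (-2.57 ± 0.43, a paralog of Hba-a2) and Alas2 (-2.44 ± 0.40), and camera gave adjusted p = 1.13e-11 and adjusted p = 0.0363 with an estimated correlation. That value was 0.153 without the 4 libraries that stand apart. Alb averaged 271 ± 468 CPM in T13_L1 with a median of 33.8, and Myh4 averaged 4595 ± 11150 CPM in L2 with a median of 643, so single libraries carried these means. Scn11a, a sensory neuron channel gene, was higher (2.26 ± 0.55, adjusted p = 0.0131), at 0.66 with adjusted p = 0.453 without the 3 T3 libraries with sensory transcripts and 0.0552 with the animal as a block.

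**Figure D4:**
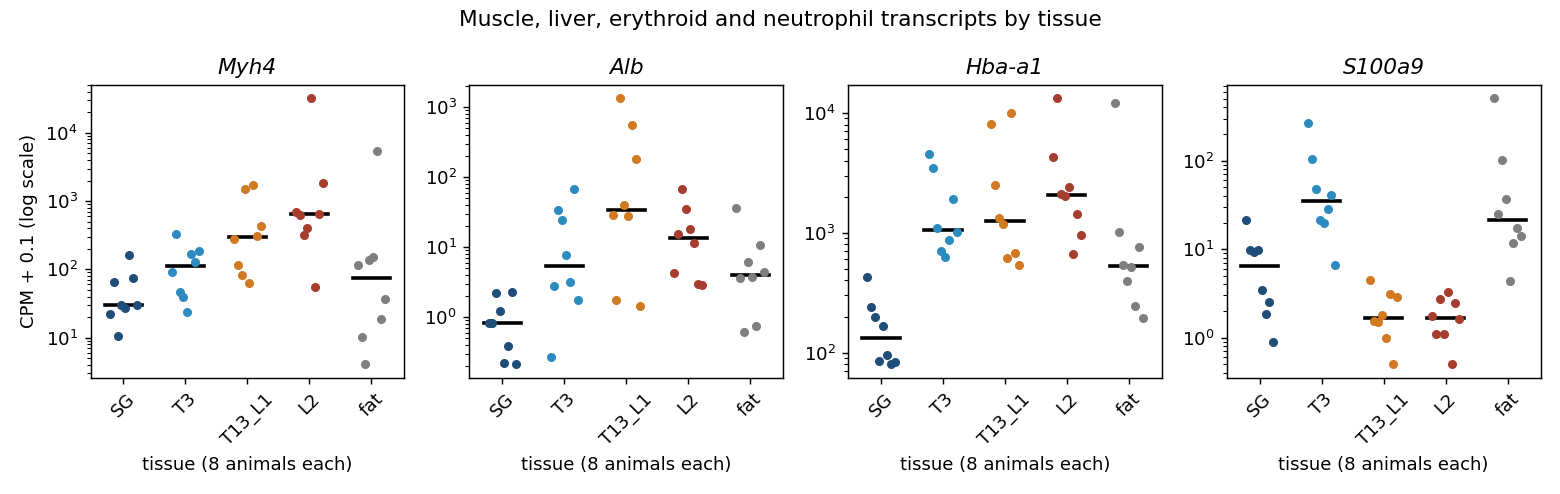
Each point is the CPM plus 0.1 of Myh4 (muscle), Alb (liver), Hba-a1 (erythroid) or S100a9 (neutrophil) in 1 library on a log scale, by tissue (8 libraries each), with bars at the median. Alb reaches 1332 CPM in 1 T13_L1 library against a median of 33.8, and Myh4 reaches 32159 CPM in 1 L2 library against a median of 643.

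The remaining lists showed few called members between upper and lower ganglia. The counts were 0 of 17 noradrenergic, 4 nicotinic, 14 brown adipocyte, 16 endothelial, 6 lymphatic endothelial, 18 fibroblast, 19 macrophage, 7 mast cell, 4 adrenal cortex, 7 mesothelial and epithelial, 10 mitochondrially encoded, 4 Y-linked, 10 X inactivation, 21 interferon and 6 MHC class II genes, for which edgeR gave the same 0 adjusted over each list alone. Counts were 1 lower in the pan-neuronal (of 22), neurotrophin (of 11), mural (of 14), lymphocyte (of 13) and cholesterol (of 22) lists, and 1 higher in the channel (of 32), clock (of 15) and sensory neuron (of 7) lists. They were 2 lower in the adipocyte list (of 28, with Retn at -1.75 ± 0.33; 3 adjusted over the list alone), and 2 higher and 3 lower in the chromaffin list (of 9). Adjusted over the list alone, 2 neurotrophin genes and 1 lymphocyte gene were higher, and 2 lymphocyte genes lower. The brown adipocyte list was up by camera (median 0.27, adjusted p = 3.77e-06, and adjusted p = 0.305 with an estimated correlation), with Ucp1 at 0.85 ± 0.39 (adjusted p = 0.312). Ucp1 was called at 1.35 with the adipocyte score as a covariate (adjusted p = 0.00953) and at 1.36 without the 4 libraries that stand apart (adjusted p = 0.0241). The noradrenergic list (median 0.17, adjusted p = 0.0427, 0.0546 with the animal as a block, adjusted p = 0.888 with an estimated correlation) was up. So were the mural list (median 0.23, adjusted p = 0.00123, adjusted p = 0.565 with an estimated correlation) and the interferon list (median 0.18, adjusted p = 0.0413, 0.212 without the 4 libraries that stand apart, adjusted p = 0.73 with an estimated correlation). The MHC class II list (median 0.14, adjusted p = 0.0364, 0.134 without the 4 libraries that stand apart, adjusted p = 0.578 with an estimated correlation) was up. The cholesterol list was down (median -0.18, adjusted p = 0.0123, adjusted p = 0.73 with an estimated correlation). Adipoq was at -0.28 ± 0.25 (adjusted p = 0.698).

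The 6 comparisons between single ganglia share libraries, so their calls are not independent of one another. Between SG and T3, 3154 genes were higher and 3563 lower in SG. SG libraries held more neuronal transcripts, with Th at 1694 ± 156 against 987 ± 386 CPM (0.82 ± 0.27, adjusted p = 0.0129), Dbh (1.25 ± 0.33), Slc6a2 (1.20 ± 0.34), Npy (0.60 ± 0.20) and Vip (0.96 ± 0.26) all higher. They held less fat RNA, with Adipoq at -1.84 ± 0.37 and Ucp1 at -2.11 ± 0.57. Sst was lower (-2.21 ± 0.34, adjusted p = 4.68e-05), and of 16 neuropeptide genes 4 were higher (5 adjusted over the list alone) and 6 lower. Cyp2j12 (2.11 ± 0.35), Crtac1 (1.99 ± 0.32) and the kinase gene Mapk10 (1.86 ± 0.29) were among the highest, and Lars2 (-4.09 ± 0.91), Clec3b (-3.80 ± 0.85) and the mesothelial gene Upk3b (-3.79 ± 0.72) among the lowest. In the noradrenergic list 16 of 17 genes were higher, in the pan-neuronal list 18 of 22 and in the cholesterol list 17 of 22 (Idi1 2.36 ± 0.46). In contrast, 26 of 28 adipocyte genes (Plin1 -3.26 ± 0.54), 13 of 14 brown adipocyte genes, 14 of 18 fibroblast genes, 11 of 16 endothelial genes (Cldn5 -2.59 ± 0.51) and 8 of 10 Hox paralogs 1 to 5 (Hoxa5 -2.06 ± 0.29) were lower. Adjusted over the list alone these counts became 15 for fibroblast genes and 9 for the Hox paralogs, with the others as given. Of these 8 lists, all called by camera, none held with an estimated correlation, the lowest value being adjusted p = 0.445 with an estimated correlation for the Hox list. With the adipocyte score as a covariate only 32 genes were higher and 41 lower, 61 of them among the 6717. Adipoq, itself part of that score, stood at 0.24 (adjusted p = 0.544). Of the genes named in this paragraph only Sst kept its call in that fit, with Npy at 0.03, Vip at 0.11 and Th at 0.15 (adjusted p = 0.973, 0.88 and 0.865). The fold changes of Calca (-4.28, adjusted p = 0.0508), Scn11a (-4.10, adjusted p = 0.0619) and Tmem233 (-5.15, adjusted p = 0.158) stayed large there. Idi1 (1.85), Cyp2j12 (1.37), Crtac1 (1.15), Mapk10 (1.04) and Lars2 (-2.35) lost their calls with fold changes less reduced than those of Th, Npy and Vip. With the pan-neuronal score 693 were higher and 793 lower, and Th stood at -0.05 (adjusted p = 0.883), Npy at 0.06 (adjusted p = 0.832) and Vip at 0.22 (adjusted p = 0.548). That score also ended the calls of Dbh (0.09), Slc6a2 (0.01), Adipoq (-0.67), Ucp1 (-0.99), Clec3b (-1.56), Cldn5 (-1.44) and Lars2 (-2.31), and Npy lost its call with genes higher in fat left out (0.40, adjusted p = 0.0712). Sensory transcripts were lower in SG, Calca by -3.37 ± 0.77 and Scn11a by -3.16 ± 0.76, but stood at 0.58 and 0.04 without 3 T3 libraries. Tmem233 (-5.71 ± 1.28) lost its call without them too (-2.06, adjusted p = 0.131).

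SG and T13_L1 differed in 37 genes higher and 187 lower in SG. Slc18a1 (1.93 ± 0.36, 44.3 ± 14.3 against 11.7 ± 5.84 CPM), Cckar (1.52 ± 0.33, 139 ± 39 against 48.1 ± 17.9 CPM), Hoxc4 (1.27 ± 0.18) and Egr1 (1.01 ± 0.25, and adjusted p = 0.067 at thinned counts and 0.0602 without a term for labelled sex) were higher. So was Dmkn (0.97 ± 0.26, adjusted p = 0.0426), which lost its call with the animal as a block (0.0827), with RLE normalization (0.0524), without an expression filter (0.0637) and without Gm42418 and mitochondrial transcripts (0.0513). Sst (-3.34 ± 0.35, adjusted p = 1.11e-07), Vip (-2.11 ± 0.26, adjusted p = 3.47e-06), Chat (-1.30 ± 0.34, adjusted p = 0.0446, and 0.0637 without an expression filter and 0.064 with the adipocyte score), Hoxc10 (-5.85 ± 0.48), Hoxc9 (-2.69 ± 0.21), Cldn19 (-3.19 ± 0.29) and Ncmap (-2.29 ± 0.22) were lower. Npy was at -0.68 ± 0.20 (adjusted p = 0.0887), and was called lower with DESeq2 (-0.71, adjusted p = 0.0147), both scores as covariates (-0.83 and -0.86), genes higher in fat left out (-0.74) and without the 4 libraries that stand apart (-0.70). Th (0.51 ± 0.26), Dbh (0.37 ± 0.32), Slc6a2 (0.71 ± 0.34), Adipoq (-0.32 ± 0.36) and Ucp1 (0.33 ± 0.55) had adjusted p from 0.423 to 0.867, and Th passed without the 4 libraries that stand apart (0.48, adjusted p = 0.0368). By camera the noradrenergic list was up (median 0.54, adjusted p = 1.82e-06, adjusted p = 0.531 with an estimated correlation) and the adipocyte list down (median -0.35, adjusted p = 7.65e-04, adjusted p = 0.751 with an estimated correlation). Of the lists, 10 of 16 myelin genes (13 adjusted over the list alone), 5 of 6 Hox paralogs 9 to 13 (6), 2 of 7 Hox paralogs 6 to 8 (3) and 7 of 9 erythroid genes (8) were lower. Their camera tests had adjusted p = 4.38e-05, 5.26e-08, 0.00662 and 0.00785 with an estimated correlation. The liver genes Serpina1c (-8.34 ± 1.52), Fabp1 (-8.26 ± 1.49), Alb (-8.10 ± 1.37) and Apoa1 (-8.05 ± 1.29) were lower, and Hba-a1 was at -4.34 ± 0.66. The count rose to 458 with DESeq2, 380 without an expression filter, 388 on the authors' shorter gene list and 611 without the 4 libraries that stand apart, and fell to 103 at 3030270 counts per library.

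SG and L2 differed in 1191 genes higher and 2083 lower in SG. Cckar (2.72 ± 0.35), Slc18a1 (2.54 ± 0.37), Crabp1 (1.80 ± 0.23) and Hoxc4 (1.64 ± 0.18) were higher in SG in 8 of 8 animals. Th (1.09 ± 0.27, adjusted p = 0.00503), Slc6a2 (1.13 ± 0.34, adjusted p = 0.0191) and Dbh (0.93 ± 0.33, adjusted p = 0.038, and 0.0588 with the animal as a block and 0.0734 without an expression filter) were higher too. Hoxc10 (-7.29 ± 0.48), Sst (-2.65 ± 0.34), Vip (-1.11 ± 0.25), Chat (-0.98 ± 0.35, adjusted p = 0.0409, and 0.098 without an expression filter and 0.0616 on the authors' shorter gene list) and Cldn19 (-2.56 ± 0.29) were lower. Also lower were fat genes (Cfd -3.20 ± 0.47, Plin1 -3.08 ± 0.54, Adipoq -2.06 ± 0.37), the mast cell protease gene Cpa3 (-2.72 ± 0.47) and the muscle genes Mylpf (-6.05 ± 1.19) and Myh4 (-6.03 ± 1.13). Npy (-0.24 ± 0.20, and called at -0.69 with the pan-neuronal score, adjusted p = 0.00431) and Ucp1 (-0.74 ± 0.55) did not pass the test. All 6 tested Hox paralogs 9 to 13 and 3 of 7 paralogs 6 to 8 were lower (6 and 5 adjusted over the list alone; adjusted p = 6.38e-06 and 0.0095 with an estimated correlation). Also lower were 25 of 28 adipocyte genes (27 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation) and 19 of 20 muscle genes (20 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). With the adipocyte score as a covariate 54 genes were called, 40 of them among the 3274, and Dbh stood at -0.05 (adjusted p = 0.983). In that fit Th (0.44), Slc6a2 (0.03), Cpa3 (-0.67) and the score's own members Adipoq (-0.09), Plin1 (-0.19) and Cfd (-0.61) lost their calls. So did Slc18a1 (1.98), Chat (-0.89), Myh4 (-3.84) and Mylpf (-4.00), whose fold changes moved less. Without the 4 libraries that stand apart 1594 were called, and with the pan-neuronal score as a covariate 367, where Th (0.49), Dbh (0.16), Slc6a2 (0.34), Chat (-1.13), Plin1 (-1.60), Myh4 (-4.61) and Mylpf (-4.46) lost their calls.

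T3 and T13_L1 differed in 2295 genes higher and 2039 lower in T3. Vip (-3.07 ± 0.27, adjusted p = 5.30e-09), Slc5a7 (-3.07 ± 0.48), Slc18a3 (-1.70 ± 0.36), Chat (-1.30 ± 0.36), Npy (-1.28 ± 0.20) and Sst (-1.13 ± 0.31) were lower in T3. The same held for Hoxc10 (-4.83 ± 0.49), Hoxc9 (-2.73 ± 0.21), Gcgr (-4.57 ± 0.68), and the liver genes F2 (-4.36 ± 1.02) and Apoa1 (-4.06 ± 0.99). Dbh was lower (-0.88 ± 0.33, adjusted p = 0.0401, and 0.0521 with the animal as a block, 0.0665 without an expression filter, 0.0598 with genes higher in fat left out and 0.0522 without 3 T3 libraries), and Th (-0.31 ± 0.26) and Slc6a2 (-0.49 ± 0.34) did not pass. The neutrophil genes S100a9 (4.84 ± 0.59), Ngp (4.57 ± 0.68) and S100a8 (4.44 ± 0.58) were higher in T3, as were the thymocyte gene Rag1 (4.54 ± 0.95, with a median of 0 CPM in T13_L1), the sensory gene Scn11a (3.85 ± 0.78, and 0.56 with adjusted p = 0.461 without 3 T3 libraries) and the fat genes Ucp1 (2.44 ± 0.58) and Adipoq (1.51 ± 0.36). Of the lists, 8 of 10 Hox paralogs 1 to 5 were higher (9 adjusted over the list alone; adjusted p = 0.0317 with an estimated correlation, and 0.0738 with the animal as a block as well). Of 6 paralogs 9 to 13, 4 were lower (5 adjusted over the list alone; adjusted p = 0.0317 with an estimated correlation). Without the 4 libraries that stand apart these 2 values were 0.15 and 0.159. Of 16 myelin genes 11 were lower (15 adjusted over the list alone; adjusted p = 0.0667 with an estimated correlation) and of 28 adipocyte genes 24 were higher (25 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). With the adipocyte score as a covariate 534 genes were called, 419 of them among the 4334, and Adipoq, itself part of that score, stood at -0.09 (adjusted p = 0.802). In that fit Sst (-0.49, adjusted p = 0.454), Slc18a3 (-0.74, adjusted p = 0.189), Chat (-1.37, adjusted p = 0.0866), Dbh (-0.11) and Ucp1 (0.74) lost their calls. The pan-neuronal score left 2119 and thinning 2867, and that score ended the calls of Sst (-0.47, adjusted p = 0.176), Chat (-1.13, adjusted p = 0.0696), Dbh (-0.09), Adipoq (0.64) and Ucp1 (1.59). Chat was lost without 3 T3 libraries as well (-0.98, adjusted p = 0.074).

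T3 and L2 differed in 178 genes higher and 358 lower in T3. Hoxc4 (1.73 ± 0.19), C1ql1 (2.83 ± 0.49), Cartpt (1.79 ± 0.31), Ngp (4.97 ± 0.70), S100a9 (4.88 ± 0.60), S100a8 (4.40 ± 0.58) and Rag1 (6.55 ± 1.14) were higher. Rag1 had at most 2 counts in an L2 library, so its fold change rests on values near the floor. In T3 it averaged 10.2 ± 13.4 CPM with a median of 5.82. Hoxc10 (-6.27 ± 0.48), Vip (-2.06 ± 0.26, adjusted p = 7.96e-06) and Npy (-0.84 ± 0.20) were lower. The muscle genes Myh4 (-4.52 ± 1.09) and Neb (-4.26 ± 1.10) were lower, with adjusted p = 0.0727 and 0.195 with the animal as a block, and stood at -2.29 and -1.40 without the 4 libraries that stand apart (adjusted p = 0.0525 and 0.153). Neb lost its call without an expression filter (-4.20, adjusted p = 0.0572) and without 3 T3 libraries (-4.54, adjusted p = 0.0685) too. Ucp1 (1.37 ± 0.56, adjusted p = 0.167) was called with the block (1.96, adjusted p = 0.0378), with the adipocyte score (1.97, adjusted p = 0.00872) and without the 4 libraries that stand apart (2.43, adjusted p = 0.00626). Th, Dbh, Slc6a2, Sst, Chat and Adipoq had adjusted p from 0.127 to 0.941, and Th passed with the pan-neuronal score (0.54, adjusted p = 0.0264). Of Hox paralogs 1 to 5, 4 of 10 were higher and of paralogs 9 to 13, 5 of 6 lower (6 and 5 adjusted over the list alone; adjusted p = 0.00515 and 1.44e-05 with an estimated correlation). These 2 values were 0.0704 and 0.0151 without the 4 libraries that stand apart. The mural list had a median of -0.07 and a mean of -0.41 but was called up by camera (adjusted p = 0.0295, 0.0953 with the animal as a block, 0.143 without the 4 libraries that stand apart, and adjusted p = 0.647 with an estimated correlation). The count rose to 3180 without the 4 libraries that stand apart, 495 of the 536 calls among them, to 1007 with DESeq2, 935 with the adipocyte score and 989 with the pan-neuronal score. It fell to 339 without the 3 T3 libraries with sensory transcripts and 228 at 3030270 counts per library.

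T13_L1 and L2, the lower pair, differed in 31 genes higher and 141 lower in T13_L1, and 127 of the 141 had been called higher in fat than in ganglia. Plin1 (-2.53 ± 0.53), Cfd (-2.13 ± 0.45), Adipoq (-1.74 ± 0.37) and the mast cell protease genes Cma1 (-2.35 ± 0.47) and Cpa3 (-2.34 ± 0.47) were lower. So were Hoxc10 (-1.44 ± 0.32, 6.85 ± 2.68 against 18.7 ± 4.9 CPM) and Hoxd9 (-1.44 ± 0.35, adjusted p = 0.0383, and 0.0597 without an expression filter). The liver genes F2 (4.20 ± 0.99) and Ambp (4.13 ± 1.03), the myelin gene Ncmap (0.90 ± 0.21), Pllp, which is not on the myelin list, and Vip (1.01 ± 0.25, adjusted p = 0.0421, and 0.0756 with the animal as a block) were higher. Th, Dbh, Slc6a2, Npy, Sst, Chat and Ucp1 had adjusted p from 0.226 to 0.653. Of 28 adipocyte genes 17 were lower (25 adjusted over the list alone; adjusted p = 0.0759 with an estimated correlation), and of 6 Hox paralogs 9 to 13, 2 (4 adjusted over the list alone; adjusted p = 0.00426 with an estimated correlation). In the myelin list 1 gene was higher (8 adjusted over the list alone; adjusted p = 0.0428 with an estimated correlation, and 0.0662 with the animal as a block as well). With the animal as a block 13 genes were higher and 57 lower, 62 of these 70 calls among the 172. Only 1 gene was called with the adipocyte score as a covariate and 0 once genes higher in fat were left out (1296 at an unadjusted p below 0.05 in edgeR). The counts were 12 without an expression filter, 21 without the 4 libraries that stand apart, 21 with the pan-neuronal score and 46 at 3030270 counts per library, against 587 with DESeq2. Of the 12 genes named above as lower or higher, the fit with the adipocyte score ended the calls of all. Adipoq, Plin1 and Cfd are members of that score, so smaller values were built into the fit for them. Adipoq (-0.24), Plin1 (-0.26), Cfd (-0.26), Vip (0.31), Cpa3 (-0.79) and Cma1 (-0.86) were far smaller there, Ncmap stood at 0.72, and Hoxc10 (-1.35), Hoxd9 (-1.26), F2 (4.80), Ambp (4.63) and Pllp (1.28) kept their size. With genes higher in fat left out Hoxc10 (-1.54) and Hoxd9 (-1.53) kept it too, at adjusted p = 0.0697 and 0.108. Calls were ended by the fit without an expression filter for all but Pllp, with fold changes within 0.1 of those above. The fit without the 4 libraries that stand apart ended all but that of Cpa3, with Hoxc10 at -1.41 and Plin1 at -2.08, and the pan-neuronal score all but those of Hoxc10 and Pllp, with Hoxd9 at -1.39 and Plin1 at -1.55. Thinning ended those of Vip (1.04), Cpa3 (-2.25), Hoxc10 (-1.29), Hoxd9 (-1.31) and Ncmap (0.92).

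Labelled sex was compared with the animal as the unit, after a look at sex-linked transcripts. Xist (chromosome X, 103460366 to 103483254), which is transcribed from the inactive X of female cells, had at least 202 CPM in the 15 libraries of animals 6, 7 and 11 and at most 9.06 CPM in the other 25. Y-linked counts (Ddx3y, Eif2s3y, Kdm5d and Uty together) were 325 or more in the libraries of animals 1, 4, 13, 14 and 16 and 49 or fewer in the rest. Animals 6 and 7 are labelled male and animals 13, 14 and 16 labelled female, so 25 of the 40 libraries carry transcripts of the sex opposite to their label. All 5 libraries of each animal lay on the same side. Between labelled females and labelled males, Xist differed by -1.19 ± 2.39 (adjusted p = 0.923) and Ddx3y by 0.45 ± 1.60 (adjusted p = 0.96) in the summed ganglia.

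**Figure D5:**
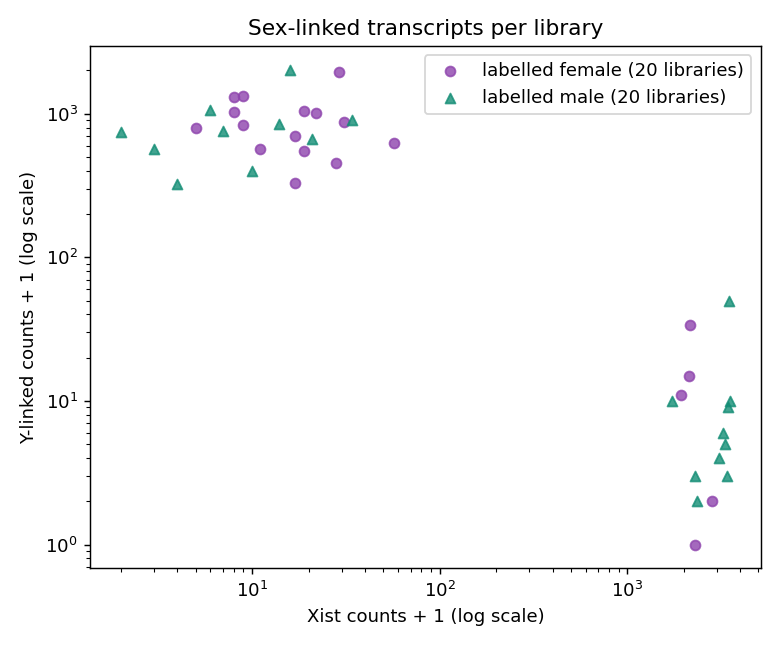
Each point is 1 of the 40 libraries, with Xist counts plus 1 on the x axis and the summed counts of 4 Y-linked genes plus 1 on the y axis, both on log scales, and color and shape for the labelled sex. Both labels appear in both clusters: 15 labelled female libraries lie among those with Y-linked counts of 325 or more, and 10 labelled male libraries among those with 49 or fewer.

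With the labels as given, edgeR called 0 genes between labelled females and labelled males in the summed ganglia (1155 at an unadjusted p below 0.05, and 37 calls with DESeq2). By tissue, edgeR called 0 in SG (899 unadjusted and 14 with DESeq2), 0 in T3 (336 and 0), 0 in T13_L1 (964 and 39), 0 in L2 (409 and 0) and 0 in fat (1127 and 12). In SG, 59 genes were called without animal 11 and 1 without animal 1 or 13. The interaction of labelled sex with upper or lower ganglia called 0 genes in edgeR (298 at an unadjusted p below 0.05, 0 with DESeq2), and that with fat 0 (1408 unadjusted, 183 with DESeq2). Because most animals carry transcripts opposite to their label, none of these counts describes female against male tissue. Labelled females 14 and 16 were also born before all other animals, so differences by label may be mixed with differences by birth date. Among the genes always reported, Sst was 0.89 ± 0.19 higher in labelled females with the 2 groups of 4 apart (adjusted p = 0.697, and 0.00932 with DESeq2). Th (0.10 ± 0.12), Dbh (0.09 ± 0.10), Slc6a2 (0.30 ± 0.12), Npy (0.12 ± 0.10), Vip (0.02 ± 0.26), Chat (-0.05 ± 0.23), Adipoq (-0.44 ± 0.31) and Ucp1 (-0.64 ± 0.34) had adjusted p from 0.718 to 0.991. Camera called 14 of 38 lists in the summed ganglia and 0 with an estimated correlation. Of these, adipocyte genes stood lower in labelled females (median -0.34, adjusted p = 3.06e-08, and adjusted p = 0.459 with an estimated correlation) with 0 of 28 members called over all genes or over the list alone.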

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

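A sample was set apart when its distance to the nearest of the other 7 in its tissue was large against the whole range of the 8 (Dixon's 95% criterion). Of 140 groups of 8 values tested, 31 held such a sample. The values were 22 genes in CPM, not on a log scale, and 6 library measures. The criterion's rate of about 1 in 20 holds for normally distributed values. Several of the genes, such as Myh4, Alb and Cldn19, were named from these same data, so the 31 is no test against chance. The groups share libraries, so several come from the same library. For the patterns weighed below, the 3 tests on the labelled sex and the test of a fixed amount of Lrrc17 reads were chosen only after the result was seen. The other tests were written before.

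Fat of animal 11 stood far above the other fat libraries in neuronal transcripts: Th at 392 CPM (the next highest 26.1), Dbh at 506 (31.7), Slc6a2 at 1097 (57.9), Npy at 297 (31.9), Vip at 12.6 (2.69), Sst at 4.41 (1.28), Cckar at 42.2 (1.29), Slc18a1 at 11.3 (1.19), C1ql1 at 4.41 (1.03) and Hoxc9 at 7.14 (1.5). The mean log2 CPM of the pan-neuronal transcripts was at 6.75 (3.14) and Lrrc17 at 11711 counts (4812). T3 of animal 1 was far from the other T3 libraries in the opposite sense, with Th at 113 CPM (the next lowest 878), a pan-neuronal score of 5.07 (7.12), Adipoq at 1024 CPM (the next highest 482), S100a9 at 265 CPM (105) and 25.7% of counts in Gm42418 (10.9%).

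Blood, muscle and liver transcripts gave most of the others. In animal 1, S100a9 was far above the rest in SG (21.3 CPM, next 9.74) and fat (509, next 101), as was Hba-a1 in SG (431, next 240) and fat (12106, next 1008), and Alb (36.4, next 10.7) and Hoxc10 (1.41, next 0.388) in fat. Hba-a1 also stood apart in L2 of animal 4 (13249 CPM, next 4324), and Hoxc10 in T3 of animal 4 (1.02 CPM, next 0.324). Myh4 stood apart in L2 of animal 11 (32159 CPM, next 1846), fat of animal 13 (5333, next 150) and SG of animal 13 (163, next 73.9). Alb stood apart in T13_L1 of animal 6 (1332 CPM, next 556). Vip was high in SG of animal 4 (72.8 CPM, next 58.2) and Cldn19 high in fat of animal 13 (7.5 CPM, next 1.43).

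The first pattern weighed is the set of 5 animals whose sex-linked transcripts go against their labelled sex. Exchanged animal numbers within the series are excluded as the only error, since only 3 animals have Xist where 4 are labelled female. An exchange together with another error stays open. Mixed RNA of both sexes is argued against for the libraries with Y-linked transcripts: their highest Xist CPM is 4.49% of the lowest in a library with Xist. In the other direction, L2 of animals 6 and 11, which have Xist, held Ddx3y at 6.53 and 5 CPM. The lowest Ddx3y in a library with Y-linked transcripts was 39.4 CPM, so some mixing in L2 of animals 6 and 11 is not excluded. A wrong sex label for whole animals stays open: all 5 libraries lie on the same side in 8 of 8 animals, but this is how the pattern was found and is no test of it. The tables do not tell at which step the labels and animals came apart, and no biological explanation was tested.

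The second pattern is Lrrc17, which took 1.5% of all counts in T3 and 0.646% in SG on average, with 33139 to 96106 counts in every ganglion library whatever its total. Within the ganglion groups the slope of its log2 counts on the log2 total was -0.16 (95% interval -0.41 to 0.09), where the median over 5083 genes was 1.08 and 1.02% of them had a slope this low or lower. A fixed amount of reads per ganglion library stays open, since this slope restates how the pattern was found. Fat libraries held only 2446 to 11711 counts despite larger totals. The slope of log2 Lrrc17 CPM was -0.38 (-0.72 to -0.03) on the pan-neuronal score and -0.63 (-1.34 to 0.08) on the satellite glia and Schwann score. A source in those cells needs a slope near 1. These slopes do not decide it, since a near constant count gives a higher CPM in small libraries. L2 of animal 4 and T13_L1 of animal 13 had the lowest totals and the lowest pan-neuronal scores of their tissues. Fat of animal 11, with the highest pan-neuronal score of the fat libraries (6.75), had the most Lrrc17 counts among them. Lrrc17 lies at 21543559 to 21575904 on chromosome 5 inside Fbxl13 on the opposite strand, and where the reads come from stays open.

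The third pattern is the liver transcripts in T13_L1. Over 14 liver transcripts not used to find it, the median log2 fold change of SG against T13_L1 was -6.35, with 13 lower and 0 higher in SG, so RNA of liver cells in T13_L1 libraries fits. Expression by the ganglion's own cells as steady as that of its peptides is argued against. These transcripts had a median SD of 2.46 on the log2 scale over the 8 T13_L1 libraries, where Vip had 0.51 and Sst 0.63. Expression in ganglion cells that varies between animals would give such a spread too, so it stays open. No biological explanation was tested beyond this one.

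Splits of the same samples into other groups were compared with the real one, 50 of the 100 tissue splits within animals because the numbers pair samples. As many calls as the real count came from 1 of 100 splits, the real one itself, in most tissue comparisons. They were ganglia and fat (10543 real, highest other 199), upper and lower ganglia (544, 156), and SG and T3 (6717, 4147). The others were SG and T13_L1 (224, 82), SG and L2 (3274, 2531) and T3 and T13_L1 (4334, 1451). That is the lowest share 100 splits can give, so they make chance unlikely there without excluding it. As many calls came from 5 of 100 for T3 and L2 (536, 1762) and 6 of 100 for T13_L1 and L2 (172, 2619), where chance cannot be excluded. For labelled sex 35 of 35 splits reached the real 0 in each test, with highest others of 15 in the summed ganglia, 44 in SG, 2 in T3, 0 in T13_L1, 1679 in L2, 0 in fat, 0 for the interaction with region and 364 for that with fat. Any split reaches a count of 0, so this does not test the labelled sex. In the 2 comparisons above another split calls several times the real count, which points to a structure of the samples other than their groups, and what that is was not tested.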

How the results depend on the processing

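The directions of the main comparisons held under most settings, and RLE normalization, the fit without labelled sex and the fit without Gm42418 and mitochondrial transcripts moved no count of calls by over 1.5 times. DESeq2 called 458 genes for SG and T13_L1, 1007 for T3 and L2, 587 for T13_L1 and L2, and for labelled sex 37 in ganglia, 14 in SG, 39 in T13_L1, 12 in fat and 183 for the interaction with fat. Without an expression filter the counts were 380 for SG and T13_L1, 12 for T13_L1 and L2, and for labelled sex 6 in ganglia, 121 in SG, 3 in T13_L1 and 1 in fat. The authors' shorter gene list gave 388 for SG and T13_L1. Thinning to 3030270 counts left 302 for upper and lower ganglia, 103 for SG and T13_L1, 2867 for T3 and T13_L1, 228 for T3 and L2 and 46 for T13_L1 and L2, from its fewer counts. The adipocyte score as a covariate left 73 for SG and T3, 54 for SG and L2, 534 for T3 and T13_L1 and 1 for T13_L1 and L2 and gave 935 for T3 and L2. It reversed Adipoq, a member of that score, in SG and T3 (0.24) and in T3 and T13_L1 (-0.09), and Dbh in SG and L2 (-0.05). Leaving out genes higher in fat gave 3768 for SG and T3, 1728 for SG and L2, 2244 for T3 and T13_L1 and 0 for T13_L1 and L2. The pan-neuronal score as a covariate gave 980 for upper and lower ganglia, 1486 for SG and T3, 367 for SG and L2, 2119 for T3 and T13_L1, 989 for T3 and L2 and 21 for T13_L1 and L2, and reversed Th in SG and T3 (-0.05). Without the 4 libraries that stand apart the counts were 1601 for upper and lower ganglia, 611 for SG and T13_L1, 1594 for SG and L2, 3180 for T3 and L2 and 21 for T13_L1 and L2. Without the 3 T3 libraries with sensory transcripts 339 were called for T3 and L2, and Calca (0.58) and Scn11a (0.04) reversed in SG and T3. For labelled sex, animals born in February gave 6 in fat, voom on 32 libraries gave 10 in ganglia, and leaving out 1 animal in turn gave 0 to 59 in SG and 0 elsewhere. Of 236 list calls over 14 comparisons, 18 held with an estimated correlation and fry called 127. Except where a cause is given, the cause was not tested.

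With the animal as a replicate block, 70 genes were called for T13_L1 and L2 instead of 172. Among genes named in the tissue comparisons the block ended the calls given beside the results and that of Gldn in ganglia and fat (adjusted p = 0.133), and added that of Ucp1 in T3 and L2. It changed no other such call. Gldn, the myelin gene called lower in ganglia than in fat, also lost its call without an expression filter (-0.80, adjusted p = 0.0545). Without the 4 libraries that stand apart it stood at -0.35 (adjusted p = 0.362).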

Other observations

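The means of 2 transcripts were ordered along the chain, highest in SG and lowest in L2. Cckar, a receptor for cholecystokinin, averaged 139 ± 39 CPM in SG, 63.2 ± 29.3 in T3, 48.1 ± 17.9 in T13_L1 and 21.7 ± 11.9 in L2 (SD, n = 8), and Slc18a1, the monoamine transporter of chromaffin granules, averaged 44.3 ± 14.3, 14.4 ± 7.68, 11.7 ± 5.84 and 7.41 ± 4.01 CPM. Cckar lies on chromosome 5 (53697776 to 53707705) and Slc18a1 on chromosome 8 (69037711 to 69089235). The order of the 4 means was not tested as a trend.

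Clock genes led the labelled-sex comparison of the summed ganglia, and were chosen after their values were seen. Dbp was at 1.45 ± 0.21 (edgeR adjusted p = 0.38), Nr1d1 at 1.13 ± 0.20, Per3 at 0.76 ± 0.13, Nr1d2 at 0.71 ± 0.12 and Nfil3 at -1.08 ± 0.21 in labelled females against labelled males. None passed in edgeR with the expression filter. All 5 were called with DESeq2 (adjusted p from 3.57e-07 for Dbp to 0.00273 for Nfil3) and by voom on 32 libraries with the animal as a random effect (3.48e-05 for Dbp to 0.0166 for Nr1d1). Without an expression filter all but Nr1d1 (adjusted p = 0.155) were called. Only animals born in February, which leaves out labelled females 14 and 16, gave smaller fold changes of the same sign in edgeR. They were 1.05 for Dbp, 1.06 for Nr1d1, 0.62 for Per3, 0.64 for Nr1d2 and -0.81 for Nfil3 (adjusted p = 0.601 each). Labelled sex overlaps in part with birth date, so the fold changes over all animals are not those of the label alone. The hour of tissue collection is not in the labels.

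The sensory neuron channel gene Scn10a averaged 14.1 ± 23.9 CPM in T3 with a median of 1.08 CPM. The mean rests on the 3 T3 libraries with sensory transcripts, at 64.6, 36.2 and 9.68 CPM in animals 4, 7 and 16, and the other 5 lay between 0 and 1.62 CPM.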
